A study of Mus musculus with 6 samples.

How the data were processed

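RNA was measured in 6 skin libraries from mice of the strain C57BL/6j. Per the labels' protocols, RNA was taken up in Trizol, messenger RNA was purified on oligo(dT) beads, and complementary DNA was primed with random hexamers. Libraries were made into DNA nanoballs and read as single-end reads of 50 bases, per the labels' protocols. Reads were aligned with HISAT, per the submitters' processing notes. Its version, the genome build, the annotation, the counting tool and any filter are not given in the sources used here. Selection of poly(A) RNA leaves out transcripts without a tail, and short single-end reads cannot always be assigned between near-identical genes. Genes with close copies, such as Chil4 and the ribosomal pseudogene Rpl34-ps1, are therefore reported as uncertain. No strand information is given, so overlapping genes on opposite strands could not be told apart.

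The authors deposited 1 table of 18824 genes with an FPKM value (fragments scaled to transcript length and to mapped reads) for each library, rounded to 2 decimals. Genes carry an Entrez number and a symbol. In 25 rows the symbol had been turned into a date, and these were renamed through the Entrez number from a RefSeq gene table of assembly GRCm38.p6, in which 18766 of the numbers were found. That table was used for names only, and no coordinates are given because the build behind the values is not given. The table holds no counts, so the depth of each library is unknown. Low values were examined for the step that 1 read would give. Among 213 values of 253 genes near the floor, 13.1% were whole multiples of the gene's smallest value within a tolerance of 0.05, against 10% by chance, so no depth could be recovered. FPKM summed to between 517764 and 553305 per library. FPKM is relative: a rise of abundant transcripts lowers the value of all others. In 3 rows a value of 0 stood beside a value of at least 10 FPKM in another library, which can be a failed assignment of reads, and none of these genes is named below.

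Libraries were grouped by their titles into CCR3 and VEH, with replicates 1, 2 and 4 in each. A test for counts was planned in case the table held them, and the planned form for normalized values was used because it does not. Values were transformed to log2(FPKM + 1), genes with at least 1 FPKM in 3 libraries were kept (13063 genes, with 5761 left out), and the groups were compared with limma 3.58.1 in R 4.3.3, with a variance trend, 2-sided tests and Benjamini-Hochberg adjustment at 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates changes of genes near the floor. A low gene can pass this filter through the group in which it is higher. No block for replicate number was used, since nothing in the labels ties equal numbers together. Means and SDs are of FPKM over 3 libraries.

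Gene lists were fixed before the data were examined: 33 lists with 563 entries, of which 544 were found in the table, 3 of them by an older or newer name. The 32 lists with at least 3 tested members were compared with all other tested genes by limma's camera with a preset correlation between genes of 0.01, adjusted over the lists. Each list was also tested with an estimated correlation, with fry, and by ranks, and its members were adjusted over the list alone. A further 24 lists and gene families were added after the data had been seen. Python 3.11.15 and matplotlib 3.10.9 were used for tables and plots.

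Genes named in the text follow a rule that was also fixed beforehand. It takes the 10 largest rises and the 10 largest falls among genes past the threshold with a group mean of at least 1 FPKM and no overlap between groups. It adds Ccr3, Il6st, the CCR3 ligands Ccl5, Ccl7, Ccl8, Ccl11, Ccl24 and Ccl28, the 4 members of each list with the smallest p, and Epx, Prg2, Siglecf, Il4, Il13 and Tslp. Other genes are said to have been chosen after their values were seen.

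The steps were tested on simulated data for the comparison of CCR3 with VEH: 5 draws of 13063 genes, with the measured means, the spreads estimated by limma and 200 genes changed in each. The limma test recovered 79.4% of genes changed by 0.5 on the log2 scale, 99.1% of those changed by 1 and 100% of those changed by 2, and 6.9% of its calls were unchanged genes. In 5 separate draws, in which only the genes of 1 list changed, camera called that list, shifted by 0.5, in 5 of 5 draws and none of 145 unchanged lists. Genes in those draws varied independently, so that result says nothing about lists whose genes vary together. Noise in the draws for the limma test was also normal and independent between genes. Recovery in the measured libraries may therefore be lower.

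Alternatives were median-centred log values, no filter, a filter of 3 FPKM, a pseudocount of 0.1, a replicate block, each library left out in turn, an adjusted p under 0.1, and a fold change of at least 2. Chosen after seeing the data were a scaling of each library to the same sum, a robust variance trend and no trend. In fits that left out a library the tested genes were kept as they were.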

Results

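Gene expression was measured by RNA-seq in whole skin from 6 samples of the MC903 model, in which a vitamin D analogue applied to mouse skin brings on inflammation that resembles atopic dermatitis. The libraries formed 2 groups of 3, named CCR3 and VEH (vehicle) by their titles, with replicates 1, 2 and 4 in each. The labels disagree on the compound given to the CCR3 group. The series names SB328437, an antagonist of the chemokine receptor CCR3, while the treatment label of these libraries names SC144, an inhibitor of the cytokine receptor subunit gp130. The groups are called CCR3 and VEH throughout, and the compound is left open. Skin without MC903 was not analysed here, so no background level without inflammation can be set beside the values.

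Values were FPKM with unknown depth. Between 12919 and 13054 genes reached 1 FPKM in each library, and the 10 most abundant genes held 6.33% to 7.01% of the FPKM sum. Across genes, which are not independent replicates, Pearson's r of log2(FPKM + 1) ran from 0.993 to 0.998 within groups and from 0.990 to 0.995 between them, and no pair of libraries was identical. The first principal component held 52.9% of the variance and separated the groups. CCR3 replicate 2 lay farthest from the VEH libraries on it (22.97) and CCR3 replicate 4 nearest to them (3.45, against -10.16 for the nearest VEH library). CCR3 replicate 4 also stood apart on the second component, which held 18.6%. Nothing in the labels says that the replicates came from separate mice, so p-values measure only the spread between these samples.

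The comparison of CCR3 with VEH asked which genes differed in inflamed skin after treatment. The largest rise was that of Zbtb16 (Entrez gene 235320), a zinc-finger transcription factor, at 8.66 ± 0.863 FPKM in CCR3 and 0.830 ± 0.072 FPKM in VEH (SD, n = 3 each), a log2 fold change of 2.40 ± 0.089 (SE). Fkbp5 (14229), a co-chaperone of steroid hormone receptors, followed with 74.0 ± 7.66 against 18.0 ± 2.91 FPKM. The transcription factor gene Klf15 (66277) stood at 12.7 against 3.34 FPKM and Pdk4 (27273), whose product restrains pyruvate dehydrogenase, at 15.2 against 4.50 FPKM. Among the largest falls, the interleukin gene Il1b (16176) dropped from 247.1 ± 20.5 FPKM in VEH to 112.6 ± 12.3 FPKM in CCR3, and the chemokine gene Ccl7 (20306) from 141.4 ± 22.5 to 61.3 ± 3.42 FPKM.

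Depp1, Fam107a, Angptl7, Tmem252 and Rasd1, a Ras-related gene first known for its induction by dexamethasone, completed the rises, with log2 fold changes of 1.63, 1.54, 1.32, 1.28 and 1.18. Rpl34-ps1, a ribosomal protein pseudogene, was listed at 0 in VEH replicates 1 and 2 and at 0.15 FPKM in VEH replicate 4, and at 3.09, 1.80 and 1.79 FPKM in CCR3, and it is uncertain, because reads of a pseudogene can be hard to tell from those of its parent gene, which was not measured here. The falls were led by Fosb, a subunit of the AP-1 transcription factor, with 0.437 ± 0.144 FPKM in CCR3 and 10.6 ± 7.01 FPKM in VEH. Chil4, a chitinase-like gene of type 2 inflammation with a near-identical copy in Chil3, stood at 6.64 against 42.5 FPKM. Atf3, Mmp12, Clec7a, Olr1, Has2 and Ccl4 had log2 fold changes of -1.37, -1.16, -1.15, -1.15, -1.10 and -1.10. Clec7a encodes a receptor for fungal glucans and Mmp12 the elastase of macrophages.

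**Figure D1:**
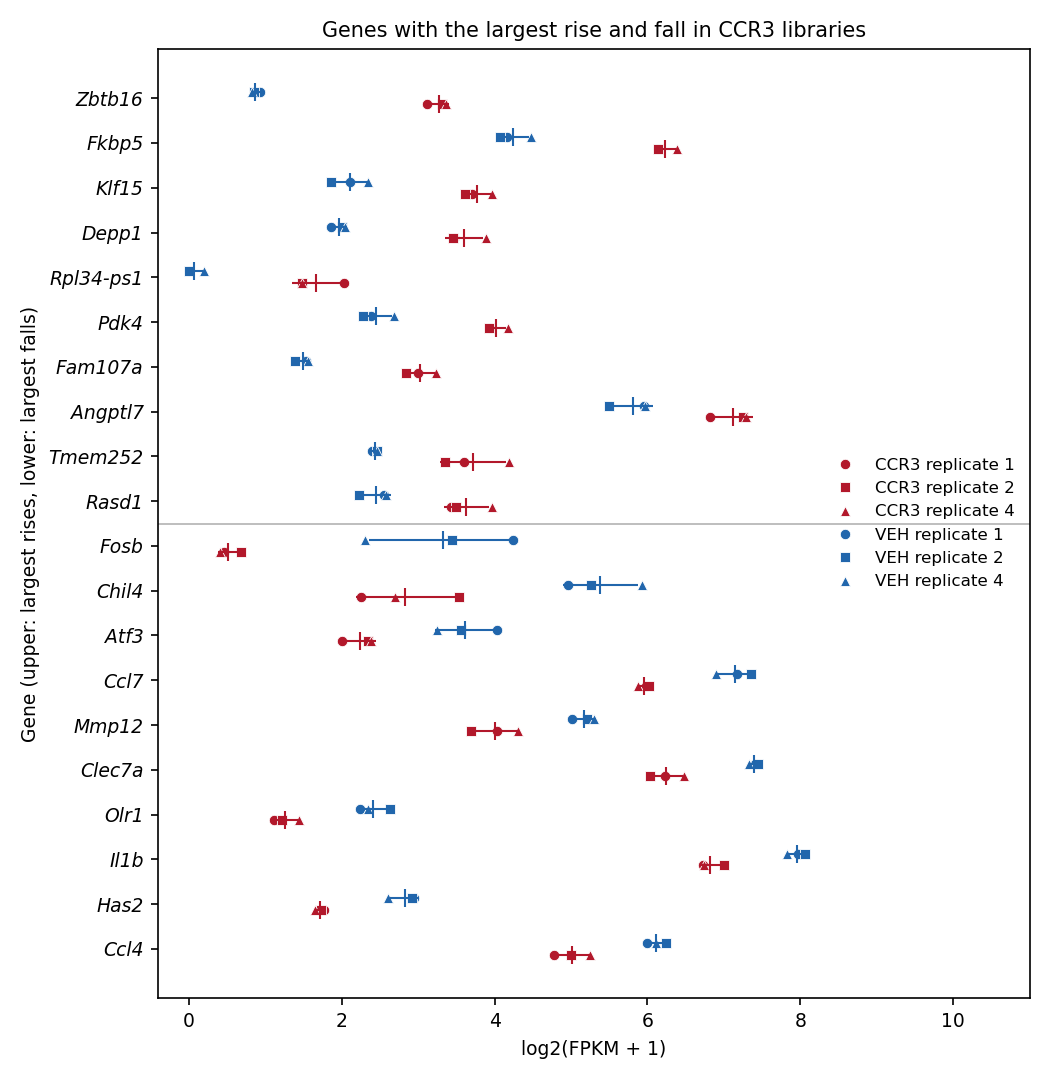
Points give log2(FPKM + 1) of the 10 genes with the largest rise and the 10 with the largest fall in each of the 6 libraries, and bars the mean ± SD of 3 libraries per group. The groups do not overlap for any of the 20 genes, which was a condition for naming them, and Fosb in VEH has the widest spread, from 3.95 to 17.91 FPKM.

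By limma with Benjamini-Hochberg adjustment, 178 genes were higher and 310 lower in CCR3 among 13063 tested, and 16 and 21 of these changed at least 2-fold. All 488 were without overlap between groups, as were 28.6% of tested genes, against 10% by chance. With median-centred values the split was 230 higher and 261 lower, and with each library scaled to the same sum it was 164 and 175. The share of higher genes thus moved from 36.5% to 46.8% and 48.4%. The number of calls depended on single libraries. It was 65 higher and 84 lower without CCR3 replicate 1, 148 and 173 without CCR3 replicate 2, and 558 and 1083 without CCR3 replicate 4. Leaving out VEH replicate 1, 2 or 4 gave 35 and 40, 52 and 68, and 28 and 46. Of the 10 largest rises, 8 stayed past the threshold without each library in turn, and of the 10 largest falls 7. Tmem252 lost it without any 1 of the VEH libraries (adjusted p = 0.0767 without VEH replicate 4). Rasd1, Chil4 and Mmp12 lost it without VEH replicate 4, with adjusted p = 0.0501, 0.0529 and 0.0655. Fosb lost it without CCR3 replicate 1 (adjusted p = 0.0545) and without VEH replicate 2.

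The receptor named by the series, and genes listed beforehand as its ligands, were compared next. Ccr3, which eosinophils and some other leukocytes carry, was 3.92 ± 0.580 FPKM in CCR3 and 5.76 ± 0.515 FPKM in VEH (SD, n = 3 each). Its 3 CCR3 values lay below all VEH values, but it did not pass (log2 fold change -0.46 ± 0.104 SE, limma adjusted p = 0.0522), and it passed without CCR3 replicate 4. Among the genes listed as CCR3 ligands, Ccl7 fell (adjusted p = 0.00318). Whether each of them binds CCR3 in mice was not examined here. Ccl24 (53.7 against 103.8 FPKM, adjusted p = 0.064), Ccl8 (1080 against 1507 FPKM), Ccl11 (16.2 against 17.8 FPKM) and Ccl5 (6.20 against 7.03 FPKM) did not pass. Ccl12 did not pass either (47.1 against 50.4 FPKM, adjusted p = 0.614). It is a member of the list outside the naming rule and was chosen after its values were seen. Ccl28 lay under the filter at 0.180 against 0.297 FPKM. As a list the 6 tested genes were lower in CCR3 than other genes by camera (adjusted p = 0.0117), 1 lower and 5 not passing, or 3 lower adjusted over the list alone. The list did not pass with an estimated correlation (adjusted p = 0.465), and its median was -0.21 without a filter against -0.34 with it.

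Eosinophil markers gave 2 lower and 8 not passing of 10 tested, 4 lower and 1 higher adjusted over the list alone, and the list did not pass (camera adjusted p = 0.0764), though it did with both scalings and without CCR3 replicate 4 or VEH replicate 1. Alox15, a lipoxygenase, fell from 17.4 to 10.7 FPKM and the ribonuclease gene Ear2, which has close copies, from 15.9 to 7.24 FPKM. Ear6, of the same gene family, went the other way, with 6.85 in CCR3 against 4.71 FPKM in VEH, and did not pass (limma adjusted p = 0.0521). Prg2, the gene of major basic protein, was 3.86 ± 1.16 against 6.36 ± 0.264 FPKM (adjusted p = 0.0612), and Siglecf 3.61 against 3.90 FPKM. Epx, the gene of eosinophil peroxidase, was near 0 in both groups (0.040 and 0.007 FPKM) and was not tested. Il6st, which encodes gp130, was 86.0 ± 6.21 FPKM in CCR3 and 80.5 ± 6.50 FPKM in VEH (adjusted p = 0.519). The list of 21 targets of gp130 and STAT3 also holds genes of ligands, such as Il6 and Osm, and of receptors, such as Il6st and Osmr. Of its genes 1 was higher and 3 lower, 2 and 8 adjusted over the list alone, and the list did not pass (camera adjusted p = 0.321). Il6 fell from 24.0 ± 0.665 to 11.5 ± 0.941 FPKM, and Bcl3 and Osm fell by 0.57 and 0.85 on the log2 scale. Osmr, the oncostatin M receptor gene, rose from 15.3 to 20.4 FPKM. Among the called genes of this list, Bcl3 alone encodes neither a ligand nor a receptor. Of the genes called in this paragraph, Il6 alone stayed past the threshold without each library in turn, and Ear2 had the highest adjusted p (0.19 without VEH replicate 4).

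Genes of type 2 inflammation and itch moved in part. The cytokine gene Il4 fell from 13.6 ± 1.97 to 6.49 ± 1.48 FPKM and Il13 from 1.42 ± 0.416 to 0.410 ± 0.106 FPKM. Arg1, which encodes arginase, fell from 500.9 to 278.2 FPKM, while Tslp, the keratinocyte cytokine that MC903 induces, was 228.1 ± 77.3 against 115.9 ± 18.1 FPKM and did not pass (limma adjusted p = 0.0868). Of 20 tested type 2 genes 5 were lower and 15 did not pass, 6 lower and 1 higher adjusted over the list alone, and the list did not differ from other genes (camera adjusted p = 0.295). Its members went both ways, 9 up and 11 down. Of 18 itch genes, 1 was higher (Osmr) and 2 lower (Osm and the histamine receptor gene Hrh4), 2 and 3 adjusted over the list alone, and the list did not pass (adjusted p = 0.651). Basophil markers were lower as a list (median log2 fold change -0.48, camera adjusted p = 0.00449, or 0.534 with an estimated correlation), with 1 of 8 genes called (Il4) and 7 adjusted over the list alone. The basophil protease gene Mcpt8 was 95.3 against 135.1 FPKM and did not pass. Mast cell markers were lower too (median -0.37, adjusted p = 0.00449, or 0.534 with an estimated correlation), with 1 of 10 genes called (Mrgprb2, the receptor gene for mast cell secretagogues) and 7 adjusted over the list alone. The lists share 3 tested genes, Fcer1a, Ms4a2 and Hdc, and without these the medians were -0.53 for basophils and -0.36 for mast cells. With all genes the medians moved to -0.29 for basophils without CCR3 replicate 2 and to -0.23 for mast cells without VEH replicate 4. Il4 and Il13 each lost their call without 4 of the 6 libraries in turn (adjusted p up to 0.0809 and 0.0972 without VEH replicate 4), Arg1 without 3 (up to 0.0951), and Hrh4 and Mrgprb2 without 4 (up to 0.0742 and 0.11).

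Several lists of immune and stress genes were lower in CCR3. All 25 interferon-stimulated genes had a negative log2 fold change (median -0.42, camera adjusted p = 5.65e-06), as did all 17 tested markers of T cells and innate lymphoid cells (median -0.37, adjusted p = 2.13e-05). With an estimated correlation neither list passed (adjusted p = 0.534 for each). The interferon list stood at -0.19 in CCR3 replicate 4 and at -0.27 in VEH replicate 4 relative to the VEH mean, so the groups overlapped. Ifit3, an antiviral gene, fell from 26.8 to 15.7 FPKM and Usp18 from 10.1 to 6.21 FPKM. Cd3g, a part of the T cell receptor complex, fell from 13.1 ± 0.695 to 8.44 ± 0.981 FPKM, and Cd4 and Cd28 fell by 0.65 and 0.55 on the log2 scale. Immediate early genes, which cells switch on within minutes of a stimulus or of tissue handling, were lower as well (median -0.29, adjusted p = 0.000161, or 0.534 with an estimated correlation), with 5 of 15 called, among them Fosb, Atf3, Ier3 and Egr2.

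The calls over all genes were 2 of 25 interferon-stimulated genes and 3 of 17 lymphoid markers, and 10 in each adjusted over the list alone, all lower. Adjusted over the list alone, 10 immediate early genes were lower and 1 higher. The list of neutrophil chemoattractants, which also holds the cytokine genes Il1b and Tnf, was lower (median -0.37, camera adjusted p = 0.0374, or 0.534 with an estimated correlation). Of its 9 tested genes 6 were negative and 3 positive. The 3 called were Il1b, Tnf (1.74 against 4.22 FPKM) and Cxcl2 (52.7 against 85.2 FPKM), and 4 were lower adjusted over the list alone. Cxcl2 was the 1 chemokine gene among those called, and Cxcl1 did not pass (limma adjusted p = 0.0661). Markers of macrophages and monocytes were lower with none of 17 genes called by limma, also adjusted over the list alone, and with 5 lower and 1 higher at an unadjusted p under 0.05 (median -0.23, adjusted p = 0.0215, or 0.714 with an estimated correlation). The macrophage list lost its call without CCR3 replicate 1 (adjusted p = 0.0934), CCR3 replicate 2 (0.13) or VEH replicate 1 (0.057), and the chemoattractants without CCR3 replicate 2 (0.115). Of the genes called here, Il1b, Tnf and Atf3 stayed past the threshold without each library in turn, and among the other named genes the highest adjusted p was 0.173 (Usp18 without VEH replicate 1). In CCR3 replicate 4 the lymphoid list stood at -0.13 relative to the VEH mean, against -0.59 and -0.45 in CCR3 replicates 1 and 2, and its median moved to -0.25 without CCR3 replicate 1. The median of the chemoattractants moved to -0.61 without CCR3 replicate 4.

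Neutrophil markers themselves did not differ from other genes (camera adjusted p = 0.38), except without CCR3 replicate 2 (0.0334). None of 13 was called by limma, 1 was higher adjusted over the list alone and 2 were higher at an unadjusted p under 0.05. Il1r2, a decoy receptor, was 139.2 ± 22.1 against 100.7 ± 4.86 FPKM and Mmp8 10.7 against 7.05 FPKM, and neither passed. Dendritic and Langerhans cell markers did not pass (adjusted p = 0.0561), with Batf3 lower among 14 (3.02 to 1.69 FPKM), also over the list alone, though no filter (0.00767), ranks (0.047), both scalings and leaving out CCR3 replicate 4, VEH replicate 2 or VEH replicate 4 brought the list past the threshold. Of 16 genes of eicosanoid synthesis 3 were lower, Alox15, Ptgs2 (47.0 to 30.1 FPKM) and Cysltr1, 5 adjusted over the list alone, and the list did not pass (adjusted p = 0.111). Of 13 endothelial and adhesion genes 3 were lower, also over the list alone: Sele, the gene of E-selectin (12.5 to 6.21 FPKM), Icam1 and Kdr. That list did not pass (adjusted p = 0.508). Of 7 markers of B and plasma cells 1, Cd79b, passed the filter and was tested, at 1.55 against 2.73 FPKM, and it did not pass. All called genes of this paragraph lost the call without at least 1 library, with a highest adjusted p of 0.184 (Kdr without VEH replicate 1).

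Epidermal and hair genes were higher in CCR3 as lists. Of 29 genes of the hair shaft and inner root sheath 10 were tested, and all 10 had a positive log2 fold change (median 0.49, camera adjusted p = 1.47e-06, or 0.465 with an estimated correlation). Without a filter on low values the median was 0.07 (mean 0.26, adjusted p = 0.00277). Tchh, the gene of trichohyalin, rose from 171.6 ± 11.6 to 257.3 ± 21.2 FPKM. Of 38 genes of the cornified envelope and barrier, 35 were positive (median 0.25, adjusted p = 1.84e-07, or 0.534 with an estimated correlation), but none was called by limma, also adjusted over the list alone, and 10 were higher at an unadjusted p under 0.05. Rptn, which encodes the envelope protein repetin, was 461.2 ± 119 against 279.2 ± 12.1 FPKM (adjusted p = 0.0728) and Flg2, the filaggrin-2 gene, 11.4 ± 2.88 against 6.78 ± 1.16 FPKM (adjusted p = 0.0746). All 10 basal keratinocyte genes were positive (median 0.21, adjusted p = 0.000161, or 0.534 with an estimated correlation) and none was called by limma, also adjusted over the list alone, with 4 higher at an unadjusted p under 0.05. Trp63, the transcription factor of basal cells, was 39.7 against 30.2 FPKM.

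The 7 tested targets of the vitamin D receptor were higher as a list (median 0.31, camera adjusted p = 0.000163, or 0.418 with an estimated correlation), with the receptor gene Vdr (13.1 ± 0.346 to 19.1 ± 0.517 FPKM) and S100g (7.80 to 15.8 FPKM) called and 5 adjusted over the list alone. In the hair list 7 genes were higher adjusted over the list alone. The cornified envelope median moved to 0.12 without CCR3 replicate 2 and to 0.46 without CCR3 replicate 4, where 16 of its genes were called. In CCR3 replicate 4 this list lay at -0.05 relative to the VEH mean, against 0.29 and 0.60 in CCR3 replicates 1 and 2. Krtap3-1, a hair keratin-associated gene, was 86.18 FPKM in CCR3 replicate 2, 27.29 and 20.96 FPKM in the other CCR3 libraries and 10.43 to 13.71 FPKM in VEH. Tchh, Vdr and S100g lost their calls without VEH replicate 1, with adjusted p = 0.0829 and 0.0509 for Tchh and Vdr, and S100g reached 0.192 without VEH replicate 4.

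Keratinocyte activation genes did not pass (camera adjusted p = 0.0639), with 2 of 39 higher, Defb3, a defensin gene (14.9 to 27.6 FPKM), and Serpinb3b (50.8 to 76.0 FPKM), and 3 higher and 1 lower adjusted over the list alone. The list passed without CCR3 replicate 4 or VEH replicate 2, and both genes lost their calls without 5 of the 6 libraries in turn (adjusted p up to 0.185 for Serpinb3b without VEH replicate 4). The interleukin-17 and interleukin-22 list (6 genes, adjusted p = 0.249), proliferation genes (23 genes, adjusted p = 0.508) and sebaceous gland genes (18 genes, adjusted p = 0.158) did not pass, and the 1 gene called in them by limma was Pparg, lower. At an unadjusted p under 0.05, 1 interleukin gene was higher and 1 lower, and 3 proliferation genes were higher and 1 lower, with none adjusted over the list alone. Of the sebaceous genes 1 was higher and 1 lower adjusted over the list alone. Proliferation genes passed without VEH replicate 2 (adjusted p = 0.012) and sebaceous genes without CCR3 replicate 4 (adjusted p = 0.000552). For proliferation, fibroblast, neutrophil, itch and sex-linked genes the median was below 0 while camera's direction relative to other genes was up, and the means of the fibroblast and neutrophil lists were above 0.

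Lists that stand for the cut of skin and for other tissues also moved. Adipocyte markers were lower (median -0.61, camera adjusted p = 0.00298, or 0.646 with an estimated correlation), with 3 of 14 genes called: Lpl, the gene of lipoprotein lipase (58.0 ± 5.29 to 31.0 ± 6.65 FPKM), Pparg and Lep. Adjusted over the list alone 7 were lower. Markers of red blood cells were higher (5 genes, median 0.50, adjusted p = 0.00614), as were those of skeletal muscle (16 genes, median 0.24, adjusted p = 0.0138) and cartilage (12 genes, median 0.13, adjusted p = 0.0422). With an estimated correlation the adjusted p of these was 0.534, 0.728 and 0.714. Only Hapln1, a link protein of cartilage matrix, was called among these 33 genes (8.89 ± 1.53 to 16.5 ± 1.25 FPKM), also adjusted over the list alone. At an unadjusted p under 0.05, limma gave 3 red blood cell genes and none of the muscle genes.

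The muscle list rested on 2 libraries. Relative to the VEH mean it stood at 0.68 in CCR3 replicate 2 and at -0.69 in VEH replicate 2, and its median was 0.05 without the first (adjusted p = 0.272) and -0.11 without the second (adjusted p = 0.729). The cartilage list lost its call with both scalings and without CCR3 replicate 2 (adjusted p = 0.0642), CCR3 replicate 4 (0.279) or VEH replicate 2 (0.556, with a median of -0.02), while the median of red blood cell markers moved to 0.27 without VEH replicate 2. The adipocyte median moved to -0.40 without CCR3 replicate 2, and Lpl, Pparg, Lep and Hapln1 each lost their calls without at least 1 library (adjusted p up to 0.174 for Lep without VEH replicate 1). Fibroblast and matrix genes (18, adjusted p = 0.392), nerve and Schwann cell markers (12, adjusted p = 0.516), melanocyte markers (5, adjusted p = 0.38) and 4 sex-linked genes (adjusted p = 0.659) did not pass, and limma called none of their genes. At an unadjusted p under 0.05 there were 1 higher fibroblast gene, 3 lower nerve genes, 1 lower melanocyte gene and no sex-linked gene, and 1 nerve gene was lower adjusted over the list alone. The fibroblast list passed without CCR3 replicate 2 (adjusted p = 0.0237). Ddx3y, on the Y chromosome, was present in all libraries at 29.08 to 32.95 FPKM.

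**Figure D2:**
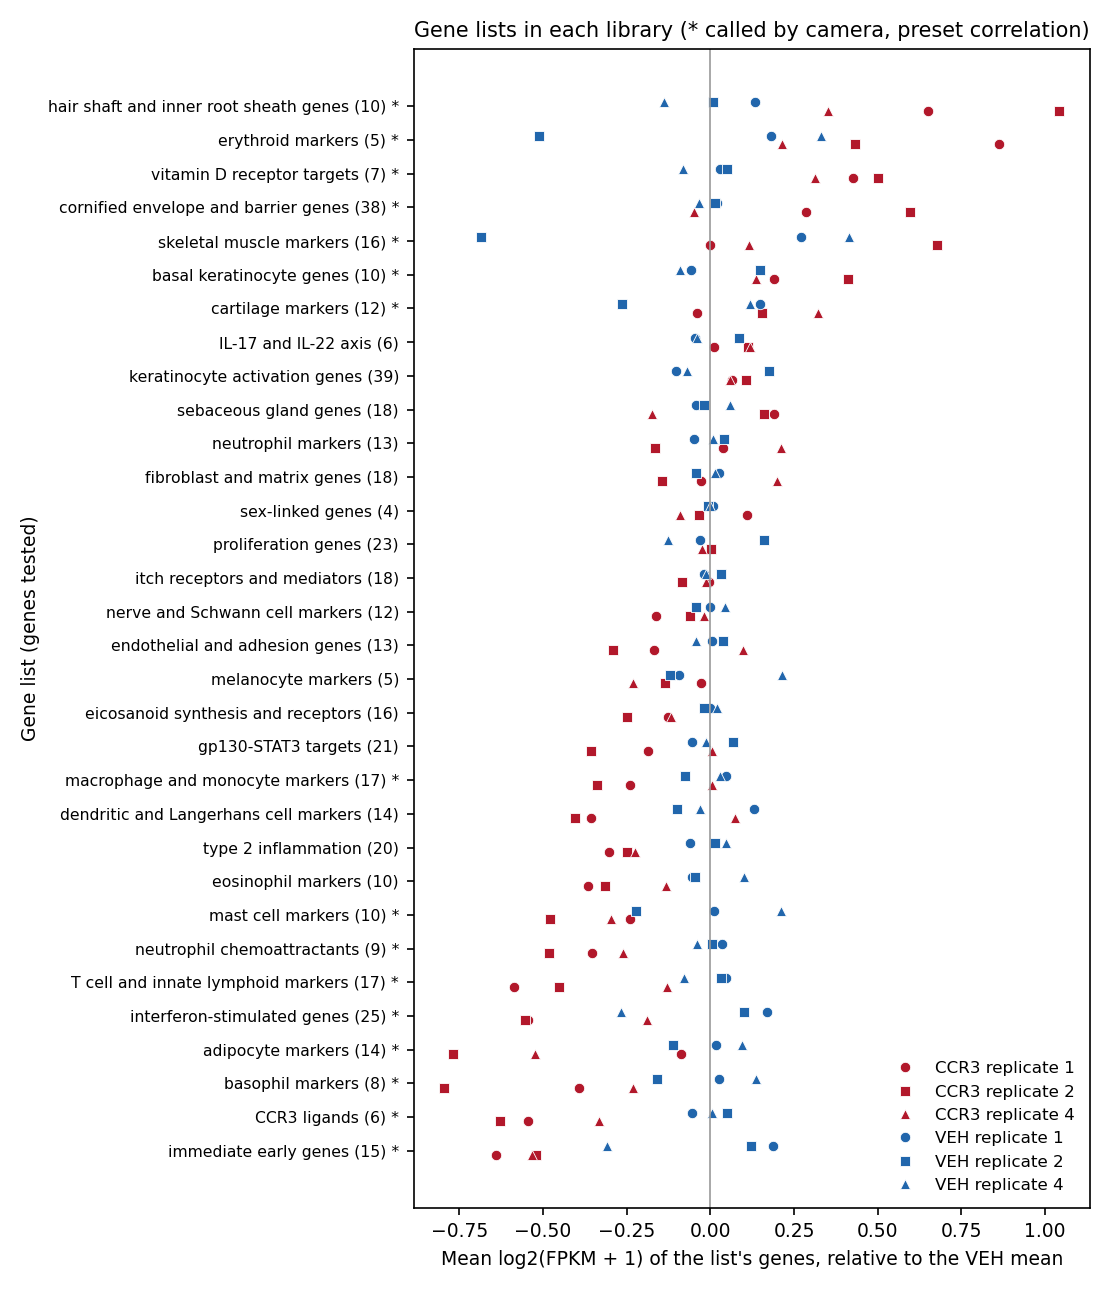
Points give, for each of 32 lists and each library, the mean log2(FPKM + 1) of the tested genes minus the mean of the 3 VEH libraries, and the number of genes tested stands in parentheses. The cornified envelope list lies at 0.60 in CCR3 replicate 2 and at -0.05 in CCR3 replicate 4, and the muscle list spans -0.69 to 0.68 across libraries of both groups.

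By camera with the preset correlation 7 lists were higher and 9 lower. Splits of the 6 libraries that mixed the groups called 5 to 16 lists in the same way. With an estimated correlation none of the 32 passed (lowest adjusted p = 0.418), and 3 had an unadjusted p under 0.05, against 19 with the preset correlation. Fry, which asks whether a list's genes move on balance in 1 direction, called 2 lists: vitamin D receptor targets (adjusted p = 0.0156) and neutrophil chemoattractants (adjusted p = 0.0263). The latter list includes the cytokine genes Il1b and Tnf. Changes in either direction passed in 16 lists. Library means overlapped between the groups in the cornified envelope, basal keratinocyte, interferon, macrophage, adipocyte, red blood cell, muscle and cartilage lists, and did not in the other called lists.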

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

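The scaling of each library to the same sum, the robust variance trend and the variance without a trend were chosen after seeing the data. Without a filter 90 genes were higher and 130 lower, with 18650 genes tested. With an adjusted p under 0.1 there were 403 and 759, and with at least a 2-fold change 16 and 21. Scaled to the same sum, 175 genes were lower (the cause was not tested). Without 1 library in turn, and so with fewer samples, 28 to 558 genes were higher and 40 to 1083 lower, the highest counts without CCR3 replicate 4. With the filter of 3 FPKM, the pseudocount of 0.1, the robust trend and no trend, both counts stayed within 1.5 times of 178 and 310. Of 55 called named genes, 0 changed direction under the settings in which they were tested (14, or 13 for those under the filter of 3 FPKM), 16 stayed past the threshold under each of these and 39 did not under at least 1. Camera with an estimated correlation called 0 lists higher and 0 lower (lowest adjusted p = 0.418), and fry called 1 higher and 1 lower, with 16 lists changed in either direction. Ranks called 15 lists: the cartilage list (adjusted p = 0.0551) and the neutrophil chemoattractants (0.148) lost their calls and the dendritic list gained one (0.047).

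A replicate block gave 89 genes higher and 144 lower, of which 196 were among the 488, and ended the call of the cartilage list (adjusted p = 0.0994). Libraries with the same number share only a number: their deviations from the group means correlated across genes at -0.064, 0.084 and -0.03 for replicates 1, 2 and 4, and CCR3 replicate 1 correlated best with VEH replicate 4 (0.144).

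Of results that changed direction, none was a called gene, and in each the cause was not tested. Siglecf ranged from -0.324 to 0.053 (log2 fold change without 1 library), Mlana from -0.243 to 0.01, Eif2s3y from -0.152 to 0.005, Uty from -0.124 to 0.06, Kdm5d from -0.01 to 0.025 and Tnnc2 from -0.006 to 0.638. The median of the muscle list ranged from -0.113 without VEH replicate 2 to 0.464 without VEH replicate 4, and that of the cartilage list turned to -0.016 without VEH replicate 2 while the direction of its test stayed. Depth is unknown, so what it limits could not be given. The planned count test (the quasi-likelihood F-test of edgeR), other count-based tests (DESeq2, limma-voom) and size factors were not run, because the table holds no counts.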

Other observations

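Several gene families that were chosen after the data had been seen also differed between CCR3 and VEH. Metallothioneins, small proteins that bind zinc and copper, were higher: Mt1 rose from 254.8 ± 29.3 to 474.3 ± 55.7 FPKM and Mt2 from 258.2 ± 17.8 to 523.8 ± 43.0 FPKM (SD, n = 3 each), 2 of 4 tested genes (camera adjusted p = 0.000193, or 0.276 with an estimated correlation). Of 13 Kruppel-like factors, a family of zinc-finger transcription factors, 3 were higher and 10 did not pass (adjusted p = 0.000124, or 0.276 with an estimated correlation). Klf9 rose from 19.4 to 40.0 FPKM and Klf13 from 21.1 to 32.9 FPKM beside Klf15, while Klf4, a factor of the epidermal barrier, was 125.2 against 113.1 FPKM. Tsc22d3, which encodes the glucocorticoid-induced leucine zipper, rose from 90.8 ± 10.9 to 203.2 ± 14.7 FPKM, and Ddit4, a stress-induced inhibitor of mTOR signalling, from 56.6 to 120.1 FPKM. Of 30 chemokines, 5 were lower and 25 did not pass (median -0.32, adjusted p = 0.000184, or 0.276 with an estimated correlation), among them Ccl2 (70.0 to 33.0 FPKM) and Ccl3 (59.9 to 28.2 FPKM), which attract monocytes. Clec12a fell from 10.1 to 5.93 FPKM among 23 C-type lectins, of which 3 were lower (adjusted p = 0.00219, or 0.322 with an estimated correlation). The 24 genes matched by an H2 symbol were mostly of MHC class I and II, but included H2-Ke6 and H2-T-ps. Of these 24, 23 had a negative log2 fold change (median -0.33, camera adjusted p = 0.000184, or 0.641 with an estimated correlation). Limma called 0 of them, and 11 were lower at an unadjusted p under 0.05. The class II genes H2-Eb1 and H2-Aa were not among these 11 (limma unadjusted p = 0.0904 and 0.0989). The median of the genes with an H2 symbol moved to -0.21 without CCR3 replicate 2 and to -0.50 without CCR3 replicate 4, and that of the Kruppel-like factors to 0.18 without CCR3 replicate 2.

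Of all 24 families and lists added this way, 7 were higher and 5 lower by camera, and 0 passed with an estimated correlation, where 3 had an unadjusted p under 0.05. The others called were keratin-associated proteins (6 of 50 genes passed the filter, which a higher level in either group helps to pass, with a median of 1.36, or 0.87 without CCR3 replicate 2), late cornified envelope proteins (21 genes, adjusted p = 0.00483, lost without CCR3 replicate 1 or 2, at 0.0545 and 0.0523), solute carriers (200 genes, 0.0128, lost without CCR3 replicate 4), cathepsins (14 genes, lower, 0.0118, lost without CCR3 replicate 2) and subunits of NADH dehydrogenase (36 genes, lower, 0.0463, lost with both scalings and without CCR3 replicate 4 or VEH replicate 4). Clock genes of the first phase and glucocorticoid-induced genes, given with the first pattern, complete the called lists. Clock genes of the opposite phase, genes of fasting, matrix metalloproteinases, collagens, guanylate-binding proteins, toll-like receptors, Wnt ligands, frizzled receptors, ribosomal proteins, small proline-rich proteins, interleukin receptors and serpins did not pass, with adjusted p from 0.0765 for serpins to 0.993 for frizzled receptors. Of these, collagens passed without CCR3 replicate 1 or 2 (higher, adjusted p = 0.0174 and 0.00194), serpins without CCR3 replicate 4 (higher, 0.0158), guanylate-binding proteins without VEH replicate 4 (lower, 0.0332) and ribosomal proteins without CCR3 replicate 4 or VEH replicate 4 (higher, 0.0158 and 0.0115).

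In the patterns that follow, the test of the glucocorticoid list without Il1r2 and Cd163 and the tests of muscle or fat, of time of day, of replicate 2 and of leukocytes alike were chosen after the results had been seen, and no biological cause other than the compound was named by the design. The first pattern was the rise of Zbtb16, Fkbp5, Klf15, Pdk4 and Tsc22d3, all known from other tissues as genes that glucocorticoids induce. Glucocorticoid receptor activity is a hypothesis, from treatment, handling or stress alike: a list of 16 other such genes, picked before its median was seen and leaving out Sgk1, Dusp1, Zfp36 and Mt1, whose values had been seen, had a median of 0.171, at the percentile 100 of 10000 random lists matched on mean expression (5th to 95th percentile -0.114 to 0.037), or 0.086 at the percentile 99.07 without Il1r2 and Cd163, which were already examined in the neutrophil and macrophage lists, with Glul and Mertk higher and 14 not passing (camera adjusted p = 0.00566, or 0.341 with an estimated correlation). Of the 16 genes, 11 had a positive log2 fold change and 5 a negative one. The percentiles take no account of genes that vary together or of the spread between libraries. They therefore cannot tie the rise to treatment. Fat carried in with the skin is argued against, since the adipocyte list fell, with a mean change of -0.46 ± 0.207 (SE). For muscle, the mean change of its list was 0.265 ± 0.403 (SE), and 1.072 with 2 SE added, below the smallest rise of the 5 genes (1.158). With 3 libraries per group, 2 SE is too narrow a bound to decide this. By library, the muscle list stood at 0 in CCR3 replicate 1 and 0.116 in CCR3 replicate 4, below VEH replicates 1 (0.27) and 4 (0.415). Zbtb16 was 7.69 and 9.35 FPKM in these CCR3 libraries and 0.91 and 0.77 FPKM in these VEH libraries. Fkbp5, Klf15 and Pdk4 did not overlap between the groups either. For Zbtb16, Fkbp5, Klf15 and Pdk4 this argues against muscle as the cause. Time of day at collection stays open: 2 of 8 clock genes of the first phase were higher, Ciart and Nr1d2 (camera adjusted p = 0.000124, or 0.322 with an estimated correlation), and the median of the opposite phase was 0.026, with -0.017 without CCR3 replicate 2, -0.021 without CCR3 replicate 4 and 0.056 with median-centred values. The compound itself, on which the labels disagree, was not tested apart from these.

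The second pattern was the higher level of epidermal and hair lists. A cause in CCR3 replicate 2 alone stays open for the cornified envelope list: its mean change was 0.118 ± 0.169 (SE) without it and 0.278 ± 0.188 with it, while CCR3 replicate 1 (0.287) lay above every VEH library, CCR3 replicate 4 (-0.05) below, and camera still called the list without it (adjusted p = 0.000188). For the hair list the mean change without it was 0.501 ± 0.168, 73.6% of that with it, and both other CCR3 libraries lay above every VEH library. This argues against that library as the whole cause only for the 10 hair genes tested, of 29 listed. Genes that reached 1 FPKM in that library alone were left out by the filter. Low genes can pass it through the CCR3 libraries, so the tested genes are in part chosen for a high level in the other CCR3 libraries too. For the basal keratinocyte list this stays open too: the mean change without it was 0.162 ± 0.080, but CCR3 replicate 4 (0.135) lay below VEH replicate 2 (0.149). How much epidermis each piece of skin held was not given in the sources used here and stays open.

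The third pattern was the lower level of immune lists. Neutrophil and lymphoid markers did not fall alike: the mean change of neutrophil markers lay above that of lymphoid markers by 0.417 ± 0.117 (SE). This contrast was chosen after both lists had been seen. The neutrophil list also holds Il1r2, counted above as glucocorticoid-induced. Its median, on which 1 gene has little bearing, was -0.039, against -0.368 for the lymphoid list. Of 13 neutrophil genes 6 were positive and 7 negative, while all 17 lymphoid genes were negative. For these lists this argues against a lower share of all leukocytes alike as the whole cause, unless expression within cells changed too. Such a change cannot be told from a change of share. A lower share of lymphoid cells and of mast cells or basophils, whose lists share genes, or lower expression within them, may underlie the pattern, and whole skin holds no value that separates these.

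The 6 libraries can be split into groups of 3 in 10 ways, so a share under 0.05 cannot be reached. The real split called 488 genes and the highest other 2, so that 1 of 10 gave as many. For lists the real split called 16 and the highest other also 16, so that 2 of 10 gave as many. Each of the other splits called lists, from 5 to 16, though none called more than 2 genes. Those splits mix the groups, so a list call with the preset correlation does not by itself set CCR3 apart from VEH.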
